A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

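The series holds 2 paired-end sequencing libraries of micrococcal nuclease (MNase) digested chromatin from budding yeast. The library labelled rsc3-1 digest is described as chromatin of an rsc3-1 temperature-sensitive strain grown at 25 °C and fixed with 0.5% formaldehyde for 1 min. The library labelled Rsc8-TAP pulldown is described as chromatin of a strain with a tandem affinity purification (TAP) tag on the RSC subunit Rsc8, grown at 30 °C, fixed with 0.5% formaldehyde for 30 min and purified on IgG beads. Both were digested with 0.0625 U MNase for 1.5 h. The cultures were of 1000 ml for the digest-labelled and 400 ml for the pulldown-labelled library, so equal units need not mean equal digestion. The libraries differ in pulldown, strain, temperature, fixation and culture volume at once, and each group had 1 library. The groups were kept as labelled, and the libraries are called digest-labelled and pulldown-labelled, because strain markers in the reads run against the labels.

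The deposited tables list each read with its position, mate distance, quality and sequence in 18 columns, with 36 bp reads and mates on adjacent lines. The authors' tables give the fragment length in bp as a signed outer distance between both ends, and a mapping quality score from 0 to 99, with no further normalization. The aligner, its settings and the genome build are not given in the sources used here. Chromatin of several aliquots of a harvest was pooled before sequencing, per the labels. The outer distance was checked against the positions of both mates and differed in 0 pairs.

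Since no reference genome was used, a consensus was built from the reads with a base quality of at least 20, and genes were placed in the coordinates of the tables as open reading frames of the annotated length. Of 6002 annotated protein-coding genes on the 16 nuclear chromosomes, 5951 were placed, with 274 of 275 tRNA genes, 59 of 76 snoRNA genes and 16 centromeres. Positions are in the coordinates of the deposited tables.

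Proper pairs of 50 to 200 bp with a mapping quality of at least 10 were kept, and copies were counted as deposited. Of 5972113 proper pairs in the digest-labelled library, 4740936 (79.4%) were used, and of 7645563 in the pulldown-labelled library 6419332 (84.0%). Fragments were counted at their midpoints and scaled to the nuclear fragments outside the ribosomal DNA, 4684521 in the digest-labelled and 6295725 in the pulldown-labelled library. Distinct pairs of ends made up 86.1% and 94.1%. At the genome mean, a stretch of 400 bp, the length of a promoter, held 156 and 209 fragments.

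Maxima of the length distribution were taken within 4 bp either side after smoothing over 3 bp. Ratios are the pulldown-labelled over the digest-labelled library, with a conditional Clopper-Pearson 95% interval of 2 counts. A promoter was the 400 bp upstream of a start codon, a coding region the first 500 bp of genes of at least that length. Regions with under 100 fragments in both libraries together were left out. A region was called higher at a ratio of at least 2 with the interval above 1, and lower at 0.5 or less with the interval under 1. Windows of 200 bp needed a ratio of 3 and at least 50 fragments. This is a rule of size and no p-value was computed. A region with 0 digest-labelled fragments entered at its bound with a floor of 3 counts. Fragments were classed as short (from 50 bp and under 120 bp), intermediate (120 to 139), nucleosome-sized (140 to 170) and long (171 to 200).

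The 16 gene lists and 5 motifs were fixed before the data were examined. Their median log2 ratios have 95% order-statistic intervals and were placed among 10000 random lists of the same size matched on the promoter fragment count, with bounds that leave 5% of random lists outside. The matched count sums both libraries, so it is not independent of the ratio. A percentile therefore compares a list with promoters of like count and not with all promoters. Named promoters were the 15 highest and 10 lowest among genes with a standard symbol, all GAL list members, the 2 highest and 2 lowest of each other list, and SCR1, RPR1, SNR6 and SNR52. Windows overlapping tRNA genes, centromeres or ribosomal DNA, or with over 10% of fragments of low mapping quality, were not eligible. This mapping quality limit stood in for the planned exclusion of repeats, which the annotation used here does not place. The marker search took pairs with 1 unmapped end within 400 bp of the RSC8 or RSC3 stop codon and matched 14 bases of the cassettes commonly used for tagging and drug selection in yeast. A tag or drug cassette is named for each strain in the deposited genotypes. Bases were compared between the libraries where each had at least 5 reads and 90% with the same base. These searches were chosen after the data were seen, and so was the minimum of 5 reads, since 10 left much of RSC3 out.

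Alternatives were each pair of ends counted once, mapping quality of at least 30 or no filter, lengths of 100 to 180 bp or up to 300 bp, scaling by the median window or by all fragments, promoters of 200 or 600 bp, no minimum count, a ratio of 1.5, single length classes, 500 bp windows, a window ratio of 2, tRNA genes with 250 bp either side, base coverage, and division within 20 GC-content bins. Division by windows of the same GC content and length thinning were added after the data were seen. The calling rule was tested on simulated data with planted changes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used with seed 20. Replication origins and long terminal repeats were not analysed here, and neither were an undigested input, a mock pulldown or a wild-type digest.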

Results

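The libraries measured where MNase-resistant DNA fragments lay in the yeast genome, and how long they were, with the GAL genes of galactose metabolism named in the series title. RSC is an essential chromatin remodelling complex that binds nucleosomes, and Rsc8 and Rsc3 are among its subunits. The library labelled rsc3-1 digest held 4740936 usable fragments and the library labelled Rsc8-TAP pulldown 6419332. Each group had 1 library and no replicates, so no spread between replicates was known and no test was run. Intervals and floors cover counting error only.

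The RSC8 and RSC3 genes, which the labels give as altered, carried markers that ran against the labels. At the RSC8 stop codon (chromosome 6, position 227501), 69 unmapped read ends in the digest-labelled library held the linker of a C-terminal tag, and 0 did in the pulldown-labelled library. No fragment passed through the intact RSC8 stop codon in the digest-labelled library, whereas 16 did in the pulldown-labelled library. Pairs with 1 unmapped end near that codon numbered 109 in the digest-labelled and 10 in the pulldown-labelled library. At RSC3 (stop codon on chromosome 4, position 1068727) the pulldown-labelled library had 12 ends with drug marker sequence and 291 pairs with 1 unmapped end, against 0 and 3 in the digest-labelled library. Fragments through the RSC3 stop codon numbered 24 in the digest-labelled and 36 in the pulldown-labelled library, and 200 bp downstream 0 and 30. Within RSC3 the libraries differed at 4 of 1885 positions with at least 5 reads in each, out of 7 such differences on the nuclear chromosomes. With at least 10 reads, 1376 positions of RSC3 were left and 0 differed. Outside the ribosomal DNA and chromosome ends, the 500 bp window at RSC3 (1068500 to 1068999) had the most such pairs in the pulldown-labelled library, 290 against a median of 3. The groups are kept as labelled below, and each direction between the libraries has to be read with these markers in mind.

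The 2 libraries differed in fragment length. The median was 91 bp (interquartile range 71 to 121) in the digest-labelled library and 129 bp (91 to 157) in the pulldown-labelled library. Short fragments, from 50 bp and under 120 bp, made up 74.1% (Clopper-Pearson 95% interval 74.1 to 74.2) of the digest-labelled and 43.6% (43.6 to 43.7) of the pulldown-labelled library. Nucleosome-sized fragments of 140 to 170 bp made up 11.89% (11.87 to 11.92) and 28.996% (28.96 to 29.03). Intermediate fragments made up 12.84% and 15.01%, and long fragments 1.16% and 12.4%. The most frequent length was 70 bp in the digest-labelled library. After smoothing over 3 bp, the digest-labelled lengths had maxima at 71, 107, 128 and 149 bp. The pulldown-labelled lengths had 9 maxima, at 76, 84, 92, 109, 116, 130, 138, 151 and 159 bp. These were unevenly spaced, by 10.4 bp on average.

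**Figure D1:**
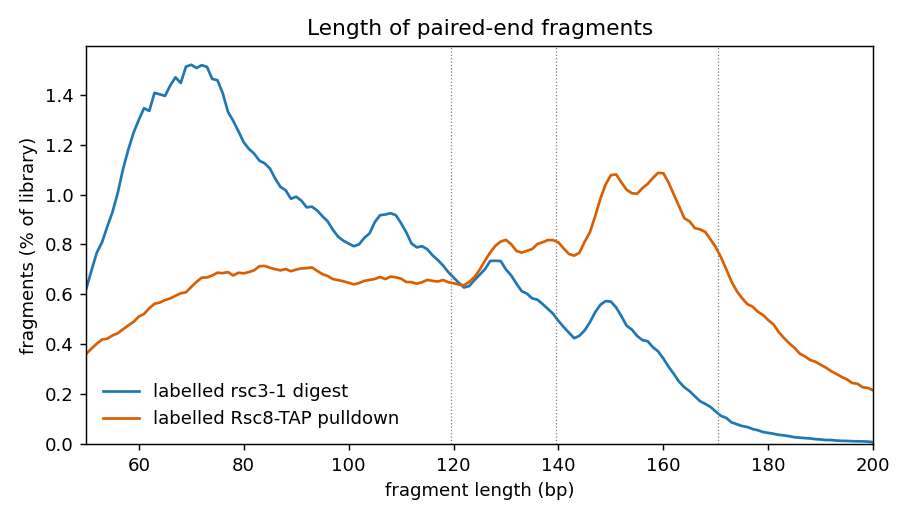
Share of fragments (%) at each length (bp) in the 2 libraries, with dotted lines between the 4 length classes. The digest-labelled curve peaks at 70 bp, and the pulldown-labelled curve extends to 159 bp and beyond with smoothed maxima spaced unevenly, by 10.4 bp on average.

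The GAL10-GAL1 intergenic region, the divergent control region of these galactose genes, lay on chromosome 2 from 278353 to 279020 (668 bp, GC content 35.9%), between GAL10 and GAL1 (start codon at 279021). It held 556 digest-labelled and 445 pulldown-labelled fragments, a ratio of 0.596 (0.525 to 0.676). Over the 3 clustered sites for the activator Gal4, the digest-labelled library had 510 fragments in 120 bp (278568 to 278687), 10.9 times its genome mean, with a median of 80 bp and 93.3% (90.8 to 95.3) short. The pulldown-labelled library had 169 there, 2.69 times its genome mean, with a median of 129 bp and 42.6% short, near its values over the whole library. Distinct pairs of ends made up 39.0% of the digest-labelled and 78.7% of the pulldown-labelled fragments there, against medians of 60.7% and 93.0% in windows of like GC content. Counted once each, they lay at 4.90 and 2.24 times the genome mean. With each pair of end positions counted once, the log2 ratio of the intergenic region went from -0.75 to 0.12, so its direction rests on how copies are counted. With fragments of 100 to 180 bp it was -0.05. Median window scaling gave -1.03 and division by windows of the same GC content -1.51, as those windows had a ratio of 1.69. That division takes the mean GC content of the whole region. The 120 bp over the Gal4 sites, at 65.8% GC, had a ratio of 0.247 (0.206 to 0.294). This lay above the 0.179 of windows in the highest GC-content bin, centred on 61.25%. The deficit after division therefore does not hold for the stretch with most digest-labelled fragments.

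The Gal4 sites were CGGATTAGAAGCCGCCG at 278568 to 278584, CGGGCGACAGCCCTCCG at 278587 to 278603 and CGGAAGACTCTCCTCCG at 278605 to 278621. Midpoints of the digest-labelled library peaked at 278603 to 278632 with 364 fragments of 80 bp median length. Pulldown-labelled midpoints peaked at 278613 to 278642 (101 fragments, median 132 bp) and at 278773 to 278802 (82 fragments, median 158.5 bp). The 56 bp amplicon used by the authors to choose the digestion, at 278530 to 278585, lies from -491 to -436 of the GAL1 start codon. It was spanned by 4 digest-labelled and 19 pulldown-labelled fragments, against chromosome medians of 13 and 36. Of the positions on that chromosome, 21.5% had fewer in the digest-labelled and 16.6% in the pulldown-labelled library.

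**Figure D2:**
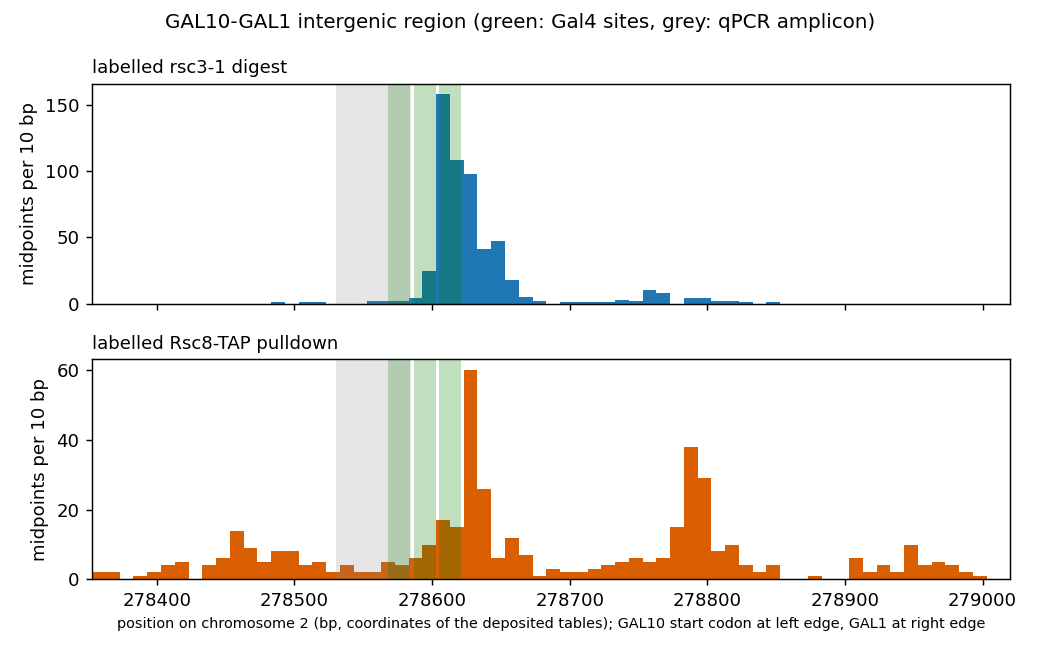
Fragment midpoints per 10 bp across the GAL10-GAL1 intergenic region, by position on chromosome 2 (bp), in the digest-labelled (top) and pulldown-labelled (bottom) library, with the Gal4 sites in green and the amplicon in grey. The digest-labelled midpoints gather at 278603 to 278632, and the pulldown-labelled ones also peak at 278773 to 278802.

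Among the 12 promoters of the GAL list, 3 were higher in the pulldown-labelled library, 1 was lower and 8 were neither. FUR4, the uracil permease, had a ratio of 15.7 (8.61 to 31.9) from 232 and 11 fragments, MTH1, a regulator of glucose transport genes, 2.79 (2.08 to 3.81), and GAL2, the galactose permease, 2.17 (1.55 to 3.08). GAL10 was lower at 0.402 (0.347 to 0.465), and its window overlaps the Gal4 sites. The GAL1 window overlaps that of GAL10 and shares part of the fragments piled up there, so calls of these 2 promoters are not separate. With each pair of end positions counted once, with fragments of 100 to 180 bp and in promoters of 200 or 600 bp, 0 GAL list promoters were lower, and GAL10 was not measured in promoters of 200 bp. Within GC-content bins, and after division by windows of the same GC content, 1 GAL list promoter was higher and 2 were lower. The bins gave 5.19 (2.85 to 10.5) for FUR4, 0.371 (0.320 to 0.430) for GAL10 and 0.400 (0.338 to 0.474) for GAL1, and neither GAL2 (1.21) nor MTH1 (0.873) was higher there. The bins take the mean GC content of a promoter, which for GAL10 and GAL1 does not match the GC-rich stretch at the Gal4 sites. Ratios of the others were 1.83 for PCL10, 1.74 for GAL7, 0.948 for GAL80, 0.874 for GAL1, 0.865 for GCY1, 0.856 for PGM2, 0.809 for GAL4 and 0.731 for GAL3. The MTH1 log2 ratio changed sign in both GC-content divisions, to -0.20 in each.

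Promoters were more often higher in the pulldown-labelled library and coding regions were not. Of 5740 promoters tested, 2701 (47.1%) were higher and 125 (2.18%) lower, with a median log2 ratio of 0.93. Of 4881 coding regions, 239 were higher and 657 lower, with a median of -0.14. These coding counts became 8 and 76 after division by windows of the same GC content, and 94 and 1117 under median window scaling. With fragments of 100 to 180 bp, 79 coding regions were higher. Relative to the genome mean, the median promoter density was 1.12 in the pulldown-labelled and 0.597 in the digest-labelled library, and the median coding density 1.13 and 1.26. Promoters had a median GC content of 36% and coding regions 40.2%. Division within GC-content bins sets the promoter median to 0 by construction, and it left 377 promoters higher and 355 lower. Division by windows of the same GC content does not centre promoters in this way, and it left 590 higher and 235 lower. Those windows include promoters and coding regions, so this division may also remove part of a difference between them. Nucleosome-sized fragments alone gave 79 higher and 48 lower of 644 promoters, and scaling by the median window shifted the promoter median by -0.29.

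The highest promoter ratios rested on few digest-labelled fragments. With 1 digest-labelled fragment each, LDB17 had a ratio of 123 (21.7 to 4878), FIG1, a mating gene, 118 (20.8 to 4673), RRN11, which encodes an RNA polymerase I factor, 117 (20.7 to 4643), TYE7, an activator of glycolytic genes, 95.2 (16.8 to 3791) and BUR2, the cyclin of the kinase Bur1, which shares its promoter with YLR225C, 88.5 (15.6 to 3526). TGL1, CTK1, GAC1, UBA3 and PFK1 had 2 digest-labelled fragments and ratios from 62.5 (17 to 520.3) for TGL1 to 48.7 (13.2 to 407) for PFK1, a phosphofructokinase subunit. URA5, with 3, shares its promoter with PML39 and had 44.6 (15 to 219). With 0 digest-labelled fragments and a floor of 3 counts, PBP4 was at least 37.5-fold, SPP41 at least 29.5-fold, MRH1 at least 28.0-fold and ITC1 at least 27.5-fold higher, where the counting intervals start at 30.1, 23.6, 22.4 and 22.0. Within GC-content bins the ratios of these 15 fell to between 4.11 for ITC1 and 20.0 for BUR2, with 18.3 (3.25 to 728) for LDB17, 17.6 for FIG1, 7.56 for UBA3 and 5.59 for PBP4. The GC content of these 15 promoters ran from 23.5% for UBA3 to 30.0% for BUR2.

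The 10 lowest promoter ratios were at LPX1, OXA1, API2, RRD1, PDR15, MHP1, ISC1, YAT1, PMP2 and ADE3. LPX1, a peroxisomal lipase gene, had 0.151 (0.126 to 0.181) from 145 and 714 fragments, and OXA1, a mitochondrial membrane insertase gene that shares its promoter with PET122, 0.187 (0.156 to 0.223). The remaining 8 ran from 0.220 for API2 to 0.291 for ADE3. Read as digest-labelled over pulldown-labelled, these 10 would rank as the highest, from 6.62 (5.53 to 7.97) for LPX1 to 3.44 (3.01 to 3.94) for ADE3. API2, RRD1, ISC1 and PMP2 share their promoters with YDR524C-B, IMP21, SPC25 and GTT3. In promoters of 200 bp, the log2 ratios of ADE3 (1.08), ISC1 (0.62), MHP1 (0.25) and RRD1 (0.15) changed sign.

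The digest-labelled density followed base composition more closely than the pulldown-labelled density did. Across 60136 windows of 200 bp within each library, Spearman's rho of the count with GC content was 0.749 in the digest-labelled and 0.180 in the pulldown-labelled library. These windows are not independent replicates. Windows with a GC content of 20 to 25% had a ratio of 10.9, and those of 55 to 60% had 0.210. The coefficient of variation of window counts was 81.6% in the digest-labelled and 36.4% in the pulldown-labelled library, against 11.3% and 9.77% from counting alone.

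**Figure D3:**
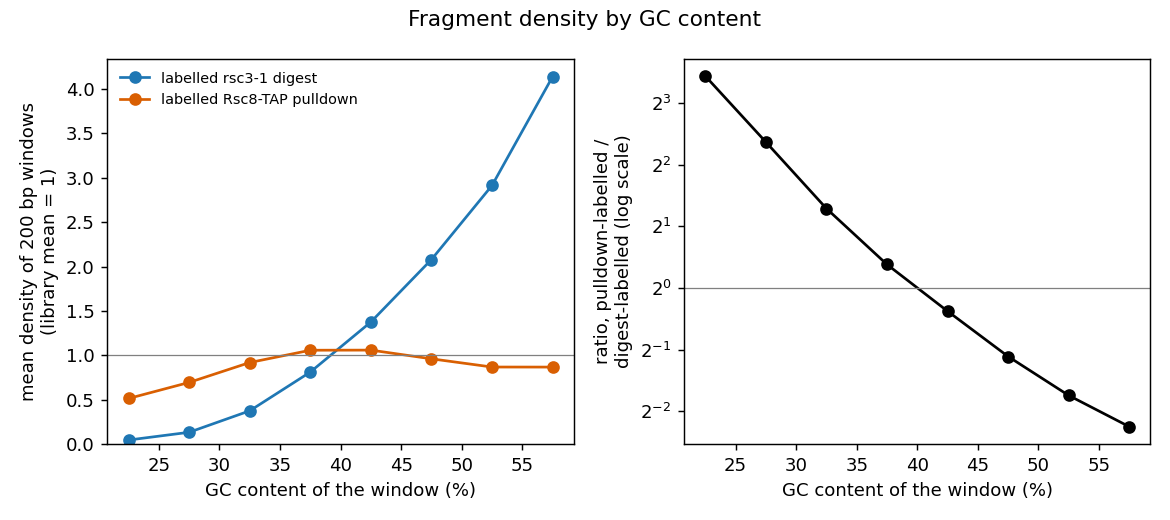
Left, mean density of 200 bp windows (library mean 1) by GC content (%) in each library, and right, their ratio on a log scale. The ratio falls from 10.9 at 20 to 25% GC to 0.210 at 55 to 60%.

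Around 5951 start codons, both libraries had a depleted region upstream and a peak at the start of the gene. The lowest density was 0.34 of the genome mean in the 20 bp bin at -100 in the digest-labelled library, and 0.84 at -80 in the pulldown-labelled library. The first peak downstream was 1.57 at +40 and 1.56 at 0. Nucleosome-sized fragments had their lowest density at -140 in the digest-labelled library (0.28) and at -80 in the pulldown-labelled library (0.60). Short fragments of the pulldown-labelled library were not depleted there, with a lowest density of 1.04 at -40 and a mean of 1.33 over the 300 bp upstream, against 0.61 in the digest-labelled library.

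**Figure D4:**
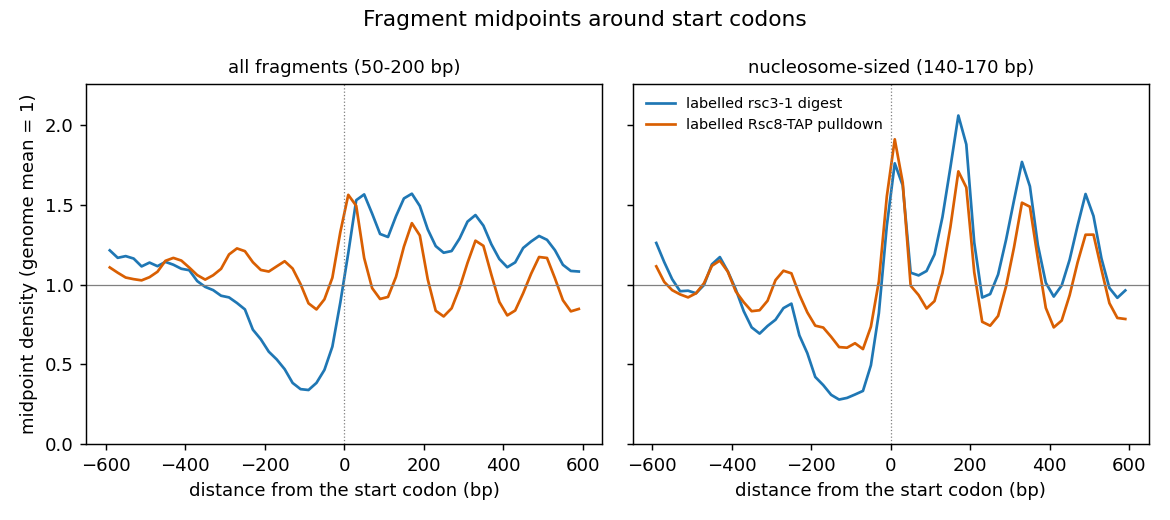
Mean midpoint density (genome mean 1) by distance from the start codon (bp) in each library, for all fragments (left) and nucleosome-sized fragments (right). The digest-labelled curve dips to 0.34 upstream, and the pulldown-labelled curve to 0.84.

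In the main analysis, promoters of glycolysis and mating genes had high ratios, and those of ribosomal protein and GAL genes low ones, against random lists of like fragment counts, but most of these positions depended on the setting. Of 16 glycolysis promoters 11 were higher and 0 lower (median log2 ratio 1.94, 0.62 to 3.13, percentile 99.6), with CDC19, pyruvate kinase, at 16.6 and ENO1, an enolase, at 0.816. Of 15 mating promoters 13 were higher and 0 lower (1.87, 1.56 to 2.18, percentile 99.93), with AGA2, an agglutinin subunit, at 15.3 and STE12, the pheromone response activator, at 1.29. Heat shock promoters had 10 of 18 higher (1.44, percentile 97.6), with YDJ1, a chaperone, at 7.78. Of 133 ribosomal protein promoters 41 were higher and 9 lower (0.43, 0.23 to 0.62, percentile 0), from 7.85 for RPP1A and RPS28A to 0.315 for RPL37A. The lower ones numbered 1 with each pair of end positions counted once, with fragments of 100 to 180 bp and in promoters of 600 bp. Within GC-content bins 3 ribosomal protein promoters were higher and 16 lower, glycolysis had 6 and 0, mating 4 and 0, and heat shock 2 and 1. The bins put RPP1A at 1.17 (0.722 to 2.02) and YDJ1 at 1.16 (0.733 to 1.94), so both calls ended, while RPS28A was at 2.45, CDC19 at 4.84 and AGA2 at 5.05. The GAL list had a median of -0.14 (-0.31 to 1.12, percentile 0.190). With fragments of 100 to 180 bp, ribosomal proteins lay at percentile 99.02, the GAL list at 3.105 and heat shock at 87.9. Promoters of 200 and 600 bp put the GAL list at percentiles 19.8 and 14, glycolysis at 77.2 and 96.9 and heat shock at 74.1 and 61.7. In promoters of 200 bp fewer were measured, 9 for the GAL list, 5 for glycolysis (median log2 ratio 2.45) and 13 for heat shock (1.56). After thinning to the digest-labelled lengths, ribosomal proteins lay at percentile 38.4, glycolysis at 82.3 and heat shock at 92.7, and with nucleosome-sized fragments ribosomal proteins lay at 99.6 and the GAL list at 88.3. Mating lay above the upper bound in each of these settings except with nucleosome-sized fragments (percentile 85.9).

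The other lists lay within the percentile bounds of the random lists in the main analysis. The matched random lists had medians from 0.23 for phosphate genes to 1.54 for meiosis, against 0.93 for all promoters. A percentile thus does not rank a list among all promoters. Under other settings some lay outside, namely ribosome biogenesis after thinning (percentile 99.78), in promoters of 200 bp (98.5) and with each pair of end positions counted once (97.66), meiosis in promoters of 600 bp (99.79) and gluconeogenesis after thinning (1.04). Respiration (97.72) and the cell wall (99.59) did so after division by windows of the same GC content. Ribosome biogenesis had 15 of 24 higher (median log2 ratio 1.67, percentile 97.4), with NOP1 at 17.3 and DRS1 at 0.929. RNA polymerases had 21 of 31 higher (1.48, percentile 94.5), meiosis 12 of 17 (1.82, percentile 88.2) and general transcription 12 of 19 (1.12, percentile 75.5). The cell wall list had 11 of 16 higher (1.23, percentile 42.1), with HSP150 at 17.5 and FKS1, a glucan synthase subunit, at 1.16. Respiration had 12 of 29 higher and 2 lower (0.84, percentile 69.7), with QCR6 at 0.346 and SDH1 at 0.411, whose log2 ratios changed sign in promoters of 200 bp (0.42 and 0.13), SDH1 also with fragments of 100 to 180 bp (0.023) and QCR6 after division by windows of the same GC content (0.55). Nitrogen catabolite genes had 6 of 21 higher (0.70, percentile 42.4) and gluconeogenesis 9 of 16 (1.02, percentile 12.1). Phosphate genes had 3 of 10 higher and 1 lower (0.63, percentile 93.5), histones 3 of 10 higher (0.26, percentile 10.0). RSC and SWI/SNF subunits had 7 of 23 higher and 1 lower (0.48, percentile 19.5), with ARP9 at 4.66 and RSC8 itself at 0.430 (0.362 to 0.509), whose log2 ratio changed sign to 0.98 in promoters of 200 bp. Of the list members named, NOP1, DRS1, YDJ1, RPS28A, RPL37A, SDH1 and RSC8 share their promoters with TSC13, COX17, MTQ1, GLN4, TOS4, AVT3 and IRC5. Because division within GC-content bins sets the promoter median to 0, it lowers the number of higher calls by construction. Most higher calls of these lists ended within GC-content bins, which left 3 higher and 3 lower for ribosome biogenesis, 2 and 2 for RNA polymerases, 1 and 0 for meiosis, 1 and 1 for general transcription, 6 and 1 for the cell wall and 1 and 2 for respiration. Nitrogen catabolite genes had 1 and 0, gluconeogenesis 0 and 1, phosphate genes 0 and 1, histones 0 and 1, and RSC and SWI/SNF subunits 0 and 4. The bins put NOP1 at 2.59, HSP150 at 3.96, ARP9 at 1.46 and RSC8 at 0.488. Within GC-content bins, glycolysis (0.71, percentile 99.97), mating (0.73, percentile 99.96), the cell wall (0.50, percentile 98.82) and phosphate genes (0.29, percentile 98.72) lay above the upper bound, and ribosomal proteins (-0.07, percentile 22.0) and the GAL list (-0.15, percentile 33.1) did not lie under the lower bound.

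**Figure D5:**
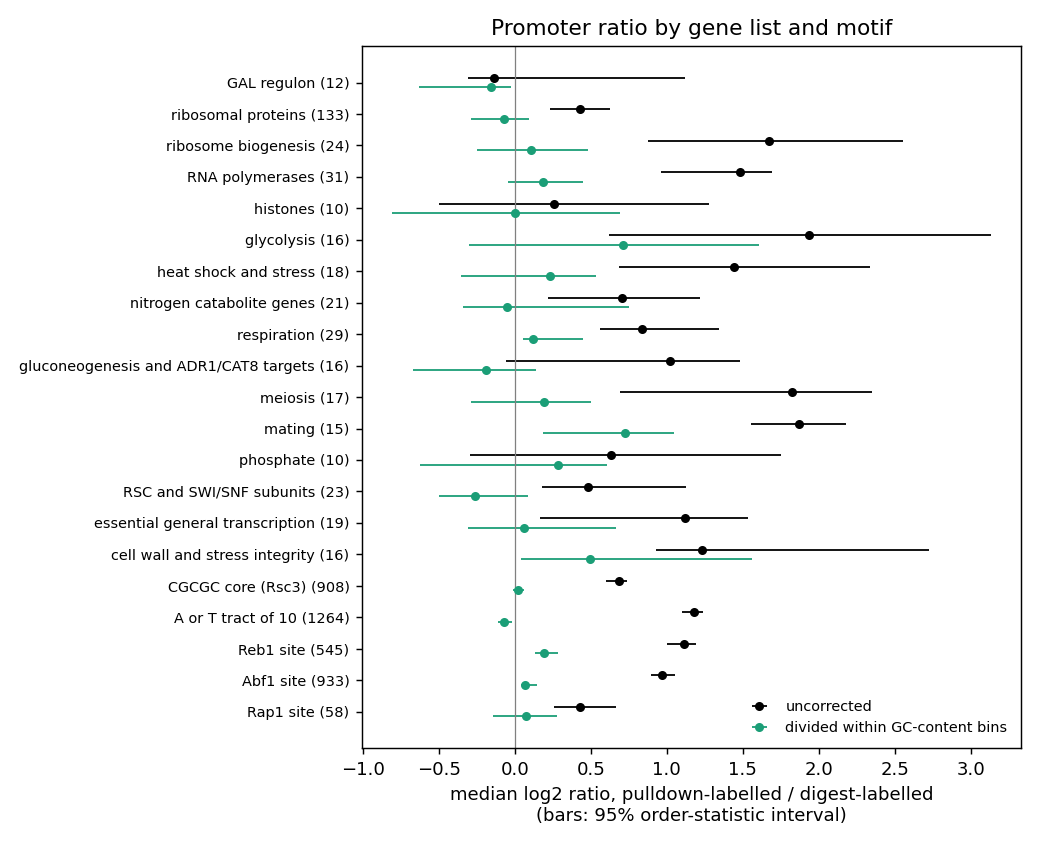
Median log2 ratio of promoters by gene list and motif, with the number measured in brackets and bars for the 95% order-statistic interval, uncorrected (black) and divided within GC-content bins (green). The uncorrected medians run from -0.14 for the GAL list to 1.94 for glycolysis, and the divided list medians from -0.26 for RSC and SWI/SNF subunits to 0.73 for mating.

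Promoters holding sites of the general regulatory factors Reb1 and Abf1 had higher ratios than random lists in the main analysis, though by little for Abf1. The median log2 ratio was 1.11 for 545 Reb1 promoters (1.00 to 1.19, percentile 100), 0.97 for 933 Abf1 promoters (0.89 to 1.05, percentile 99.7) and 0.43 for 58 Rap1 promoters (0.26 to 0.67, percentile 1.09). It was 0.68 for 908 promoters with CGCGC, the core bound by Rsc3 (0.60 to 0.74, percentile 7.07), and 1.18 for 1264 with A or T tracts (1.10 to 1.24, percentile 84.6). The matched random lists had medians of 0.94 for Reb1 and 0.89 for Abf1. The Abf1 interval holds the median of all promoters, 0.93. With fragments of 100 to 180 bp, Reb1 lay at percentile 83.6 and Abf1 at 39.9, within the bounds, while Rap1 lay at 99.04 and A or T tracts at 99.99. In promoters of 600 bp Abf1 lay at percentile 85.9, and in those of 200 bp Rap1 at 67.8. CGCGC lay under the lower bound with each pair of end positions counted once (percentile 1.88) and in promoters of 600 bp (1.74), and at percentile 89.4 after thinning. At the Reb1 sites themselves, the density was 0.302 of the genome mean in the digest-labelled and 1.52 in the pulldown-labelled library, and at Abf1 sites 0.684 and 1.48. At A or T tracts it was 0.108 and 1.03. At CGCGC sites the libraries had 1.41 and 1.42, and at Rap1 sites 1.70 and 1.56. Within GC-content bins the A or T tract median changed sign to -0.07 (percentile 0), and the CGCGC median was 0.02 (percentile 99.98). Reb1 (0.19) and Abf1 (0.07) lay at percentile 100 in these bins, and Rap1 (0.07) at 94.9, within the bounds. After thinning Reb1 lay at percentile 100, Abf1 at 99.99 and Rap1 at 63.7.

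Transfer RNA genes had more fragments in the pulldown-labelled library, with a ratio of 1.97 (1.94 to 2.01) over 274 genes with 100 bp either side, where windows of the same GC content gave 1.29. Their log2 ratio of 0.98 became 1.90 with fragments of 100 to 180 bp and 0.51 without a mapping quality filter. The 4 other RNA polymerase III genes had 0.697 (0.628 to 0.773) together. Among them, the U6 gene SNR6 had 6.32 (3.28 to 13.7), SCR1, the signal recognition particle RNA gene, 0.749 (0.640 to 0.875), and RPR1, the RNase P RNA gene, 0.474 (0.405 to 0.554), while SNR52 held 27 pulldown-labelled and 0 digest-labelled fragments. At their GC content, windows had 0.226 for SCR1, 0.302 for RPR1, 1.099 for SNR6 and 3.63 for SNR52, so SCR1 and RPR1 lay above their windows. The 58 snoRNA genes had 1.30 (1.24 to 1.36). The 16 centromeres held 73 and 0 fragments, at least 18.1-fold higher at a floor of 3 counts, where the counting interval starts at 14.4. Their GC content of 15.3% lay under the lowest GC-content bin of windows, centred on 23.75% with a median ratio of 27.3. The ratio of windows of the same GC content was 0.620 for the other RNA polymerase III genes, 1.87 for snoRNA genes and 1.12 for subtelomeric regions. Subtelomeric regions of 20 kb had 1.16 (1.15 to 1.17), a repeated class whose log2 ratio changed sign without a mapping quality filter (-0.25) and under median window scaling (-0.08). Other RNA polymerase III genes (log2 ratio 0.17) and snoRNA genes (-0.53) changed sign after division by windows of the same GC content, and the former also with fragments of 100 to 180 bp (0.72).

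High-ratio windows fell more often outside coding regions than in them, in promoters, tRNA genes and the remaining windows alike. Of 56488 windows of 200 bp with at least 50 fragments, 8266 (14.6%) had a ratio of 3 or more and 2052 had a low ratio. The high ones made up 36.6% of promoter windows, 37.7% of tRNA gene windows, 35.0% of windows elsewhere and 6.74% of coding windows. Of the low ones, 49 lay in promoters, 1930 in coding regions, 0 in tRNA genes and 73 elsewhere. After division by windows of the same GC content 1758 were high. This division sets the median of windows of each GC content near 1, so the fall in number follows in part by construction. They made up 11.4% of promoter windows, 18.3% of tRNA gene windows, 8.05% of windows elsewhere and 0.517% of coding windows. That division left 792 low. Using 500 bp windows 1340 were high and 523 low, and fragments of 100 to 180 bp gave 3905 high and 1056 low. Under median window scaling 3440 were low.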

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

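No test in this part was chosen after a result was seen, and no explanation was tested here. Signal outside the comparisons was measured because it lay above the limit that a count of 0 allows in the same library. The mitochondrial chromosome held 0.416% (Clopper-Pearson 95% interval 0.410 to 0.422) of the fragments used in the digest-labelled library and 1.63% (1.62 to 1.64) in the pulldown-labelled library. Without a mapping quality filter, the ribosomal DNA repeats on chromosome 12 held 10.9% (10.9 to 10.9) of digest-labelled and 3.07% (3.06 to 3.09) of pulldown-labelled fragments of 50 to 200 bp. Pairs longer than 200 bp made up 0.195% (0.191 to 0.198) of digest-labelled and 4.25% (4.24 to 4.27) of pulldown-labelled pairs. With 1 library per group, the differences between the libraries were not tested.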

How the results depend on the processing

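The division by 200 bp windows of the same GC content, the thinning to a common length distribution and the list medians from nucleosome-sized fragments with a minimum of 30 were chosen after the data were seen. The counts of lists and motifs past the percentile bounds were also added then. The other alternatives were set before the data were examined. No paired analysis was possible because each group held a single library. Values here are log2 ratios of the pulldown-labelled over the digest-labelled library unless a count or a length is named, and reversed marks a change of sign where the main interval, or the call of a promoter, excluded 0. Some list medians whose main interval holds 0 changed sign too, and these are named without that word. The cause was not tested for any of these changes, except that the 500 bp windows and the minimum of 100 nucleosome-sized fragments leave fewer regions to call. Only 644 promoters reached that minimum. The direction in which each ratio is read depends on the strain labels, which the markers at RSC8 and RSC3 run against.

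With each pair of end positions counted once, 79 promoters were lower, the promoter median was 0.87 and the coding median -0.18. The median length was 95 bp in the digest-labelled and 128 bp in the pulldown-labelled library, and 82 bp over the Gal4 sites in the digest-labelled library. The depleted region upstream of start codons had a digest-labelled density of 0.35. The GAL1-GAL10 ratio reversed to 0.12. The tRNA genes were at 1.05, the other RNA polymerase III genes at -0.14 and promoters with A or T tracts at 1.10. Without a mapping quality filter, the digest-labelled median length was 90 bp and its depleted region density 0.37. The tRNA genes were then at 0.51, and the subtelomeric regions reversed to -0.25. At a mapping quality of at least 30 the subtelomeric regions were at 0.24, and scaled by all fragments at 0.20. With fragments of up to 300 bp, the digest-labelled median length was 89 bp.

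With fragments of 100 to 180 bp, 1767 promoters were higher and 83 lower, 79 coding regions were higher, and 3905 high-ratio and 1056 low-ratio windows were counted. The promoter median was 0.67, the coding median -0.17 and the gap between them 0.83. The digest-labelled median length over the Gal4 sites was 116 bp. The depleted region density was 0.32 in the digest-labelled and 0.72 in the pulldown-labelled library. The GAL1-GAL10 ratio was -0.053, tRNA genes 1.90, snoRNA genes 0.26 and subtelomeric regions 0.16, and the other RNA polymerase III genes reversed to 0.72. List medians were 1.18 for ribosomal proteins, 1.40 for mating and 0.79 for the cell wall, with 3 lists past the percentile bounds. Motif medians were 0.59 for CGCGC, 0.86 for A or T tracts, 0.75 for Reb1, 0.65 for Abf1 and 1.08 for Rap1. The SDH1 promoter reversed to 0.023. From nucleosome-sized fragments alone, 79 promoters were higher and 48 lower, with a median of 0.18. From short fragments alone the median was 1.19. From nucleosome-sized fragments with a minimum of 30, list medians were 1.55 for ribosomal proteins, 0.86 for ribosome biogenesis, 0.79 for RNA polymerases, 1.17 for mating and 0.89 for the cell wall, with 1 list past the percentile bounds.

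Scaled by the median 200 bp window, 258 promoters were lower, 94 coding regions higher and 1117 lower, and 3440 low-ratio windows were counted. The promoter median was 0.64, the coding median -0.43 and the GAL1-GAL10 ratio -1.03. The tRNA genes were at 0.70, other RNA polymerase III genes at -0.81 and snoRNA genes at 0.094, and the subtelomeric regions reversed to -0.075. List medians were -0.42 for the GAL regulon, 0.14 for ribosomal proteins and 0.55 for respiration. Motif medians were 0.40 for CGCGC, 0.89 for A or T tracts, 0.83 for Reb1, 0.68 for Abf1 and 0.14 for Rap1.

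For promoters of 200 bp, 61 were lower, the median was 1.28 and 3 lists were past the percentile bounds. Medians were 1.03 for ribosomal proteins, 1.47 for histones, 1.44 for respiration, 1.07 for CGCGC, 1.53 for A or T tracts, 1.59 for Reb1, 1.44 for Abf1 and 1.11 for Rap1. Reversed promoters were RSC8 (0.98), SDH1 (0.13), QCR6 (0.42), ADE3 (1.08), ISC1 (0.62), MHP1 (0.25) and RRD1 (0.15). For promoters of 600 bp, 202 were lower, the median was 0.62 and 3 lists were past the percentile bounds. Medians were 0.52 for respiration, 1.21 for mating, 0.028 for RSC and SWI/SNF subunits, 0.74 for the cell wall, 0.44 for CGCGC, 0.73 for A or T tracts, 0.72 for Reb1 and 0.61 for Abf1. At a ratio of 1.5, 323 promoters were lower. In 500 bp windows, 1340 were high and 523 low, and at a window ratio of 2, 14842 were high and 5755 low.

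Divided within GC-content bins, 377 promoters were higher and 355 lower, and the promoter median is 0 by construction. List medians were -0.069 for ribosomal proteins, -0.049 for nitrogen catabolite genes and -0.26 for RSC and SWI/SNF subunits, which all reversed. Gluconeogenesis changed sign too, from 1.02 (-0.06 to 1.48) to -0.19. The others were 0.11 for ribosome biogenesis, 0.19 for RNA polymerases, 0.23 for heat shock, 0.12 for respiration, 0.19 for meiosis, 0.73 for mating, 0.061 for general transcription and 0.50 for the cell wall. The A or T tracts reversed to -0.073, and medians were 0.022 for CGCGC, 0.19 for Reb1, 0.068 for Abf1 and 0.074 for Rap1. The GLN1 (-0.95) and MTH1 (-0.20) promoters reversed. Divided by windows of the same GC content, 590 promoters were higher and 235 lower, 8 coding regions higher and 76 lower, and 1758 windows high and 792 low. The promoter median was 0.20 and the gap to coding regions 0.32. The GAL1-GAL10 ratio was -1.51, tRNA genes 0.62 and subtelomeric regions 0.051, while other RNA polymerase III genes (0.17) and snoRNA genes (-0.53) reversed. List medians were 0.15 for ribosomal proteins, 0.39 for ribosome biogenesis, 0.40 for RNA polymerases, 0.55 for heat shock, 0.44 for respiration, 0.37 for meiosis, 0.96 for mating and 0.73 for the cell wall, and RSC and SWI/SNF subunits reversed to -0.12. Gluconeogenesis changed sign here as well (-0.051). Motif medians were 0.27 for CGCGC, 0.10 for A or T tracts, 0.40 for Reb1 and 0.30 for Abf1. Reversed promoters were CYT1 (-0.24), MLS1 (-0.00080), GLN1 (-1.27), MTH1 (-0.20) and QCR6 (0.55).

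After thinning the pulldown-labelled library to the digest-labelled lengths, the promoter median was 1.04, the coding median -0.23 and the gap 1.27. The pulldown-labelled median length over the Gal4 sites was 105 bp. Medians were 0.75 for ribosomal proteins, 0.82 for CGCGC, 1.26 for Reb1, 1.11 for Abf1 and 0.69 for Rap1.

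Among the results that answer a comparison, 286 values stayed within their interval, or within 1.5 times a count, 143 moved and 11 reversed. Among single promoters and secondary values, 896 stayed, 367 moved and 15 reversed. The centromere ratio is a bound and was not recomputed. The division within GC-content bins leaves coding regions as they were, and it is not given for them. Replication origins and long terminal repeats, named in the plan, were not run. The GAL list median of -0.14 (-0.31 to 1.12) changed sign with each pair of end positions counted once (0.23), with fragments of 100 to 180 bp (0.12), in promoters of 200 bp (0.91) and 600 bp (0.040), after thinning (0.022) and with nucleosome-sized fragments (0.95). The histone median changed sign under median window scaling (-0.025). Depth limited the most extreme promoters, whose ratios rest on 0 to 3 digest-labelled fragments.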

Other observations

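Tests chosen after the result was seen were those of the strain markers, of fragment copies over the Gal4 sites, of the fragment length over the Gal4 sites in the pulldown-labelled library, of promoter density in the digest-labelled library, and of promoters and coding regions of equal GC content. The list percentiles from nucleosome-sized fragments and from each library alone were chosen then as well. Division by windows of the same GC content and length thinning were also chosen after the data were seen, though the bounds for their values were written beforehand.

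The strains share deletions of selectable genes, and the reads of both libraries together left gaps there. The longest run without reads was 1496 bp at LEU2 on chromosome 3 (90985 to 92480), 2239 bp at MET17 on chromosome 12 (732291 to 734529), 611 bp at URA3 on chromosome 5 (115944 to 116554) and 173 bp at HIS3 on chromosome 15 (722262 to 722434). LEU2, MET17, URA3 and HIS3 encode enzymes of leucine, methionine, uracil and histidine synthesis.

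After division within GC-content bins, glycolysis, mating, cell wall and phosphate promoters lay at percentiles 99.97, 99.96, 98.82 and 98.72 of random lists. Before it, glycolysis (99.6) and mating (99.93) lay above the upper bound, and the cell wall (42.1) and phosphate genes (93.5) did not. In the pulldown-labelled library alone, their GC-divided densities lay at percentiles 8.82, 77.6, 13.4 and 85.7, and in the digest-labelled library alone at 0, 0.355, 0.15 and 20.1. With nucleosome-sized fragments and the same division, they lay at percentiles 93.9, 87.2, 54.9 and 90.6, all within the percentile bounds of the random lists. The minimum of 30 fragments behind these last values was chosen after seeing that 100 left few promoters. Predictions on this pattern were written and then withdrawn after these values were seen, because the number of patterns weighed is limited, so it is given as values without a verdict. In that same measure, ribosomal protein promoters had a median log2 ratio of 1.32 at percentile 100, GAL promoters were at percentile 99.4 and respiration at 99.4.

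The strain markers at RSC8 and RSC3 ran against the labels. A hypothesis is that the 2 libraries, files or labels were exchanged, since 100% of the cassette ends at each gene were in the library labelled with the other strain. A wrong label on a single library is argued against, because at the RSC8 stop codon 2 libraries ran against their label, the digest-labelled one with 69 tag ends and the pulldown-labelled one with 16 intact fragments. Mixing of a large share of the other library into the digest-labelled one is argued against. There 0 fragments passed through the intact RSC8 stop codon beside 69 tag ends, at most 4.35% at a floor of 3 counts. Tag ends and fragments through the codon were counted by unlike rules, so that share is no measured mixing fraction. A small admixture stays open. Mixing into the pulldown-labelled library also stays open, since 0 tag ends beside 16 intact fragments allow up to 18.8%. Whether an exchange arose in the cultures, the sequencing lanes or the deposit was not tested, and under it every ratio direction given here would invert, with the library rich in short fragments being the Rsc8-TAP pulldown.

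Promoters lay above coding regions in the ratio by 1.07 on the log2 scale. Division by windows of the same GC content left 29.6% (27.5 to 32.1) of that gap and removed 70.4%. Regions of equal GC content in bins of 2.5 points left 37.7% and removed 62.3%. The 29.6% fell between the bounds of 25% and 50% written beforehand, so that rule gives no decision. Its interval lies above 25%, but reading it by its interval was decided after it was seen. The windows of the same GC content include promoters and coding regions, so dividing by them may also remove part of a difference unrelated to base composition. Both corrections match the mean GC content of a region and not its distribution within the region. Base composition as the whole cause therefore cannot be excluded. A difference in length distribution is argued against as the whole cause, since 119.02% (115 to 123) of the gap remained after thinning. With fragments of 100 to 180 bp in both libraries the gap was smaller, at 0.83. The promoter median was 0.18 with nucleosome-sized fragments, from 644 promoters, and 1.19 with short fragments, from 5556. The minimum count left unlike sets of promoters, so these 2 medians cannot show whether the ratio varied with the length class. RSC bound at promoters stays open as a hypothesis under the labels as given. Density over GC-matched windows in the pulldown-labelled library was 1.10 for promoters, between the bounds written beforehand, but also 1.06 for coding regions. Under exchanged labels the values to read would be those of the digest-labelled library, 0.961 and 1.14. There the 0.961 would fall on the side written beforehand as against RSC at promoters. That bound was set for the pulldown-labelled library, and the digest-labelled value was added after the result was seen.

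Fragments piled up over the Gal4 sites in both libraries, 93.3% of them short in the digest-labelled library, against 74.1% of that whole library, and 42.6% in the pulldown-labelled library, against 43.6%. In the pulldown-labelled library the count of 169 (144.5 to 196.5) lay at percentile 100 of 23 windows of like GC content, whose highest count was 102, which argues against base composition for that count. The digest-labelled count of 510 (467 to 556) also lay at percentile 100, but its interval holds the highest count of 493 and the upper percentile bound of 481, so base composition cannot be told apart there. That reading replaced a stricter one based on the percentile alone after the value was seen, and with each pair of ends counted once the density was 4.90 times the genome mean, between the bounds of 2 and 5, and the count of 199 lay at percentile 69.6 of the same windows, so copies of fragments could account for part of it. The median lengths lay at percentiles 42.9 in the digest-labelled and 64.3 in the pulldown-labelled library among windows with at least 50 fragments, so GC-rich DNA alone may account for them, and bound Gal4 or a nucleosome held there was not tested.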
